A study of Arabidopsis thaliana with 28 samples.

How the data were processed

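Closed flower buds of Arabidopsis thaliana were profiled by sequencing polyadenylated RNA in 4 genotypes, with 2 libraries of each: Col, the Columbia control, and the mutants ibm1, ibm1 jmj27 and pds5. The series also lists 20 chromatin immunoprecipitation and input libraries (histone H3, H3K9 dimethylation and GFP-tagged IBM1), which were not analysed here. Per the labels' protocols, messenger RNA was selected on poly(A) beads, libraries were made with the VAHTS mRNA-seq V3 kit, and paired reads of 150 bp were sequenced on an Illumina NovaSeq. The labels give chambers with long days and chambers with short days, both at 22 °C, without saying which library came from which, and they give no time of harvest.

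The deposited values are raw counts per gene, in 3 tables that each pair the Col libraries with 1 mutant. The authors' tools, per the submitters' processing notes, were HISAT2, Subread and DESeq2 with the TAIR10 build. Their versions, the annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here. Counts of near-identical gene copies, such as ZYP1A and ZYP1B, the RBCS genes and the LHCB1 genes, and of overlapping or antisense genes are therefore uncertain. Every row of the tables was a gene, and 0 columns of per-sample values were left unmapped.

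The tables held 27416 genes, of which 26719 had a row in a RefSeq table of the TAIR10.1 assembly and 10376 had a symbol there. That table was used for names and for the order of neighbouring genes. Its coordinates are not printed, since the authors' build differed. For 36 symbols of the gene lists it held no such name, JMJ27 and the PDS5 genes among them, and those genes were matched by locus identifier alone.

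The Col columns held the same values in all 3 tables, so the 8 libraries were fitted together in R 4.3.3. Counts were scaled with the TMM method and filtered with filterByExpr in edgeR 4.0.16, which left 21548 genes. The edgeR quasi-likelihood test with robust estimation compared a mean per genotype, with 4 residual degrees of freedom shared by all comparisons. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, with no minimum fold. Log2 fold changes are given with a standard error (SE). It was taken as the absolute log2 fold change over the square root of the F statistic of the test. This SE can fall below counting error where a group holds few counts, as for VGD1, ACA9, BBX16, BBX31, cPT4, CYP71A13 and PR1. Levels are counts scaled by the TMM library sizes (CPM) with the standard deviation (SD). A fold against a group at 0 was bounded with a floor of 3 counts over the group, and a ratio resting on 1 to 3 counts carries an exact 95% Poisson interval. Such bounds and intervals cover counting error only.

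Gene groups were described through 15 lists with 304 genes, covering demethylases, cohesin, meiotic recombination, meiotic cell cycle, DNA and H3K9 methylation, tapetum and pollen wall, pollen, floral organ identity, stomatal lineage, photosynthesis, defense, DNA damage response, mitotic cell cycle, heat stress and the circadian clock. Each list was tested in 4 comparisons, 60 tests in all, with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and an inter-gene correlation preset at 0.01. The calls were adjusted together by the Benjamini-Hochberg method. The photosynthesis, tapetum, pollen, floral organ, heat and clock lists were included to watch tissue makeup, stage, handling and harvest time. Their shifts may therefore come from the mix of buds collected as well as from the mutations. Camera with an estimated correlation and the rotation test fry were alternatives.

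The groups, tests, lists, alternatives and the rule for named genes were chosen before the data were examined. By that rule the text names IBM1, JMJ27 and PDS5A to PDS5E. It further draws on the 6 higher and 6 lower genes with the largest fold change in each comparison among genes past the threshold, with a symbol and a mean log2 CPM of at least 1, whose mutant libraries both lay outside the range of the control libraries. It also draws on up to 4 members of each list with the smallest p. TOC1, GI, LUX and PRR7 of the clock list and PDS5A to PDS5E beyond their list ranks were named to show the measured clock state and the targeted family, the clock genes after the data were seen.

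Alternatives were DESeq2 size factors in edgeR, no filter on low counts, the DESeq2 1.42.0 Wald test, each pair of genotypes fitted alone, a term for the replicate number, each library left out in turn, a minimum absolute log2 fold change of 1, an adjusted p under 0.01 and a fit without robust estimation. The comparison of ibm1 jmj27 with pds5 was added after seeing the data. Shared Col libraries make comparisons alike by chance, so 20 sets of unchanged groups were simulated against them.

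The pipeline was tested on simulated data over 21547 genes, with 200 genes changed per mutant. For ibm1 against Col it recovered 40.3% of genes changed by 0.5 on the log2 scale, 85.1% of those changed by 1 and 92.4% of those changed by 2, and 7.64% of its calls were false. For ibm1 jmj27 against Col these shares were 56.7%, 74.6% and 90.9%, with 9.20% of calls false. For pds5 against Col they were 47.8%, 86.6% and 95.5%, with 13.5% false. For ibm1 jmj27 against ibm1 they were 50.7%, 79.5% and 93.2%, with 7.76% false. The false shares lay above the nominal 0.05, and the simulations held far fewer changed genes than the real data. In pds5, beyond the 200, a list of 22 genes was shifted by -0.3 on the log2 scale. Calls of these genes did not count as false, and they entered none of the recovered shares. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.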

Results

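RNA was sequenced from closed buds, which hold anthers before and during pollen formation, of 4 genotypes with 2 libraries each. The series title places the study in male meiosis and the removal of H3K9 methylation, a histone mark of silent chromatin. IBM1 and JMJ27 encode JmjC-domain H3K9 demethylases, and PDS5 proteins are accessory factors of cohesin, the ring complex that holds sister chromatids together. Total counts ran from 19490663 in Col replicate 1 to 26038662 in pds5 replicate 1, and the most abundant gene took 0.569% to 0.832% of the counts. Replicates differed by more than sampling noise in every genotype. Chi-square per degree of freedom was 2.34 in ibm1, 2.95 in Col, 5.78 in pds5 and 15.0 in ibm1 jmj27, so no library was a copy of another. The labels do not say that replicates came from separate plants, so all p-values measure only the spread between these samples, which may be technical. All values rest on n = 2 libraries per genotype, and adjusted p-values of single genes are from the edgeR quasi-likelihood test.

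The targeted genes were examined first, since they check the labels. IBM1 (AT3G07610) stood at 54.0 ± 2.12 CPM (SD) in Col, 20.6 ± 0.869 in ibm1 and 54.7 ± 1.37 in pds5. Its log2 fold change against Col was -1.39 ± 0.0838 (SE, adjusted p = 4.98e-08) in ibm1 and -1.43 ± 0.0833 (adjusted p = 7.55e-09) in ibm1 jmj27. JMJ27 (AT4G00990) fell by 2.94 on the log2 scale in ibm1 jmj27 (adjusted p = 8.56e-12), from 64.3 ± 0.511 to 8.37 ± 0.0367 CPM, while its change was 0.19 in ibm1 (adjusted p = 0.0596, passing at 0.27 without ibm1 replicate 1, at 0.19 with a replicate block and at 0.18 with both genotypes fitted alone) and -0.08 in pds5 (adjusted p = 0.368). In pds5, PDS5A (AT5G47690) fell by 6.15, PDS5B (AT1G77600) by 3.91, PDS5C (AT4G31880) by 1.84 and PDS5E (AT1G15940) by 0.88 on the log2 scale, and PDS5D (AT1G80810) was at 0.10 (adjusted p = 0.249). PDS5A also fell in ibm1, by 1.15 on the log2 scale (adjusted p = 2.73e-07), and stood at -0.06 in ibm1 jmj27 (adjusted p = 0.544), where it passed at -0.17 when ibm1 jmj27 replicate 2 was left out. In ibm1 PDS5E also fell, by 0.46, and PDS5D rose by 0.26. The PDS5D call ended under the DESeq2 test and when Col replicate 1, Col replicate 2 or ibm1 replicate 2 was left out. PDS5B at 0.05 and PDS5C at -0.13 did not pass in ibm1 in the joint fit. The labels do not say which PDS5 genes the pds5 line lacks.

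**Figure D1:**
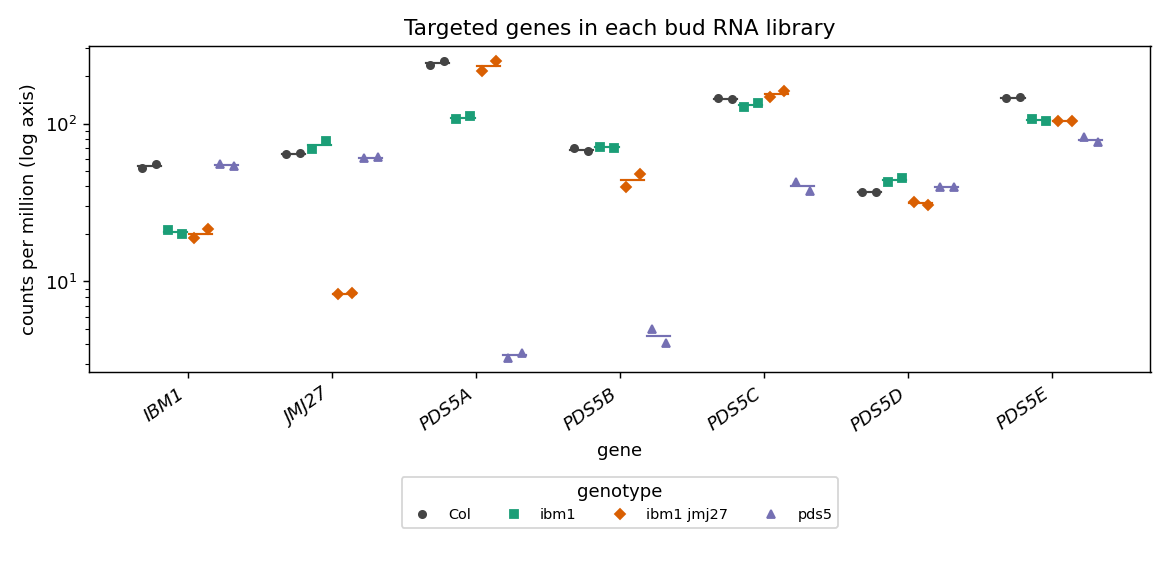
CPM (log axis) of IBM1, JMJ27 and PDS5A to PDS5E in each library, with both replicates as points and their mean as a line. IBM1 stands at 20.6 in ibm1 against 54.0 in Col, and PDS5A at 3.41 in pds5 against 242 in Col.

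Circadian clock genes differed between all 4 genotypes. The morning genes LHY and CCA1, which encode Myb repressors of the evening genes, stood at 2.93 ± 0.111 and 5.14 ± 0.524 CPM in Col. LHY was at 19.6 ± 1.32 CPM in ibm1, 493 ± 12.4 in ibm1 jmj27 and 602 ± 7.33 in pds5, and CCA1 at 49.4 ± 1.39, 193 ± 11.7 and 380 ± 1.40 CPM. The evening genes TOC1, GI, ELF4 and LUX fell in each mutant, with LUX at -1.47, -2.69 and -2.73 and GI at -0.79, -2.60 and -2.24 on the log2 scale in ibm1, ibm1 jmj27 and pds5. All 12 clock genes of the list passed the test in each of the 3 mutants, with 5 rising and 7 falling in ibm1 and 4 rising and 8 falling in ibm1 jmj27 and in pds5, the same counts as adjusted over the list alone. As a set the list passed in no mutant against Col (camera adjusted p = 0.785, 0.0579 and 0.0718). Camera asks for a shift in 1 direction, and this list moved both ways, so that outcome says little. Fry for changes in either direction passed it in ibm1, ibm1 jmj27 and pds5 (adjusted p = 2.33e-06, 1.65e-07 and 1.65e-07), as it did nearly every list. PRR7 rose in ibm1 and fell in the other mutants. Genotype and clock state could not be separated in any comparison with Col, nor between ibm1 jmj27 and ibm1, where LHY differed by 4.66 and all 12 clock genes passed. Between ibm1 jmj27 and pds5, LHY differed by -0.29 on the log2 scale, but 9 of the 12 clock genes were lower and 1 higher (camera adjusted p = 0.00185 over the 15 lists, and adjusted p = 0.502 with an estimated correlation), with CCA1 at 193 against 380 CPM.

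**Figure D2:**
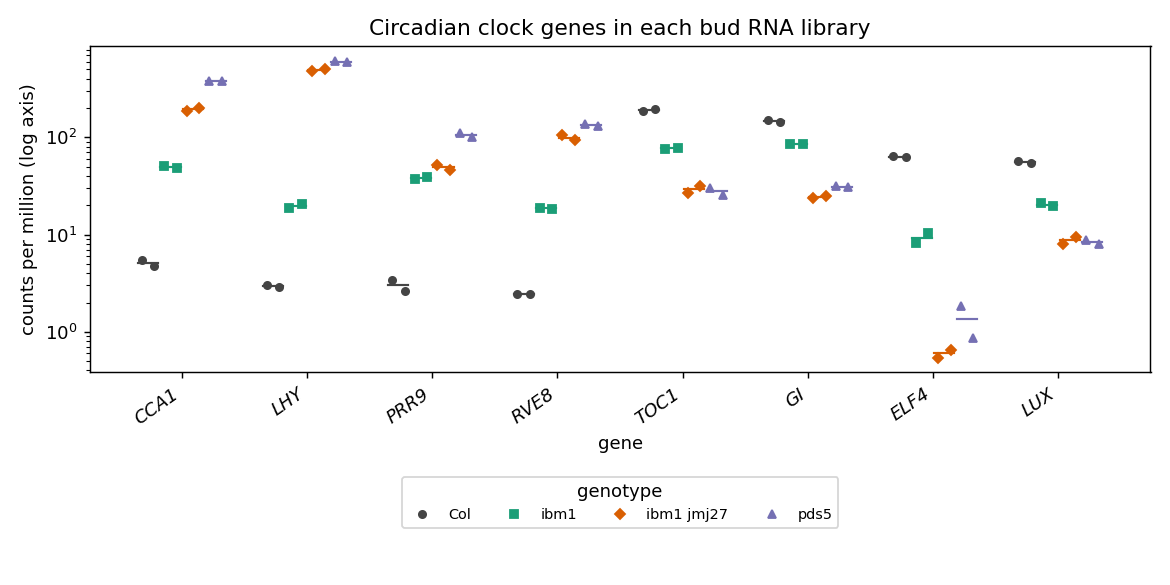
CPM (log axis) of 8 circadian clock genes in each library, with both replicates as points and their mean as a line. LHY climbs from 2.93 in Col to 19.6 in ibm1, 493 in ibm1 jmj27 and 602 in pds5, and ELF4 stands at 63.5 in Col and 9.31 in ibm1.

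The comparison of ibm1 with Col asks which bud transcripts differ when IBM1 is reduced. Of all genes tested, 31.0% passed there, the share to set beside the list counts. Of the listed genes, 19 of 22 for photosynthesis rose and 17 of 28 for the tapetum, the anther layer that feeds the developing pollen, and the pollen wall fell, and neither list passed with an estimated correlation (adjusted p = 0.569 and adjusted p = 0.594). LHCB1.1 and LHCB2.1, which encode light-harvesting proteins, rose by 2.46 and 2.35 on the log2 scale. VGD1, a pectin methylesterase of the pollen tube, fell by 1.61, from 83.9 ± 1.78 to 27.5 ± 1.52 CPM. The iron-response regulators bHLH38 and bHLH39 rose from a single count in Col to 411 and 181 counts, ratios of 410 (95% interval 73.3 to 16250) and 181 (95% interval 32.0 to 7178). FSD1, an iron superoxide dismutase, rose by 3.92 ± 0.267 on the log2 scale, CYP71A13 of camalexin synthesis by 4.77 ± 0.341, AFP1, an abscisic acid signalling gene, by 3.92 ± 0.120 and LEA7 by 3.74 ± 0.110. The largest falls, among genes with a reference symbol and a mean log2 CPM of at least 1, were those of COR27 (-3.86 ± 0.139), NAI2 (-3.69 ± 0.427), the demethylase gene JMJ30 (-3.02 ± 0.148), BSMT1 (-2.79 ± 0.498), the clock gene ELF4 (-2.77 ± 0.150) and MIOX4 (-2.55 ± 0.311). The call of BSMT1 ended when any 1 of the 4 libraries was left out (adjusted p = 0.0507 to 0.0692).

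Of 28 tapetum and pollen wall genes, 17 fell and 0 rose in ibm1 (18 and 0 adjusted over the list alone), with a median of -0.73. The callose synthase gene CALS5 fell by 1.06 and QRT3, needed to separate microspores, by 0.67. The list passed camera (adjusted p = 2.20e-09), with adjusted p = 0.594 with an estimated correlation. Of 27 measured pollen genes, 13 fell and 2 rose (14 and 2 adjusted over the list alone), with a median of -0.78 and camera adjusted p = 0.000348, and adjusted p = 0.240 with an estimated correlation. Of 22 photosynthesis genes, 19 rose and 1 fell (20 and 1 adjusted over the list alone), with camera adjusted p = 4.88e-09, and adjusted p = 0.569 with an estimated correlation. Of 18 mitotic genes, 7 fell and 0 rose by either adjustment, adjusted over the list alone or over all genes, with the D-type cyclin gene CYCD3;1 at -0.41 (camera adjusted p = 0.00797, and adjusted p = 0.594 with an estimated correlation). Of 14 meiotic cell cycle genes, 4 fell, led by TDM1 at -1.86 ± 0.289, and 6 fell adjusted over the list alone (camera adjusted p = 0.0446, and adjusted p = 0.569 with an estimated correlation). That call ended without Col replicate 2, without ibm1 replicate 2 and with a term for the replicate number (camera adjusted p = 0.0515). LHY was higher by 2.74 on the log2 scale in these ibm1 libraries. Whether a different mix of bud stages moved these lists in ibm1 was not tested.

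Lists that did not pass camera in ibm1 held changed members, in a comparison where 31.0% of all genes tested passed. Of 43 meiotic recombination genes, 3 rose and 6 fell, the same as adjusted over the list alone. HEI10, a crossover factor, rose by 0.86 ± 0.152 and MND1, needed for strand invasion, fell by 0.60 ± 0.121 (list adjusted p = 0.547). Of 22 cohesin genes 3 rose and 3 fell (adjusted p = 0.240), and of 30 DNA and H3K9 methylation genes 3 rose and 7 fell (adjusted p = 0.146), the same counts as adjusted over the list alone in both lists. CLSY1 and RDR2 of RNA-directed DNA methylation fell by 0.61 and 0.70. In the DNA damage list 4 of 17 genes rose and 2 fell by either adjustment, adjusted over the list alone included, with ANAC044 at 2.02 ± 0.229 and the cell cycle inhibitor SMR5 at 2.60 ± 0.467 (adjusted p = 0.432). The demethylase list held 4 risen and 4 fallen genes of 17 (5 and 4 adjusted over the list alone, adjusted p = 0.512), floral organ identity 2 and 7 of 18 (adjusted p = 0.244), stomatal lineage 1 and 0 of 10 (0 and 0 adjusted over the list alone, adjusted p = 0.733), defense 1 and 3 of 13 (adjusted p = 0.968) and heat stress 0 and 1 of 6 (adjusted p = 0.498), with the floral, defense and heat counts unchanged when adjusted over the list alone. The median and mean of the clock list differed in sign (-0.68 and 0.30, test lower), as did those of the defense list (0.09 and -0.12, test lower), and the meiotic recombination list had a median of 0.00 and a mean of -0.06 (test lower).

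In total 6680 of 21548 genes passed in ibm1, 3552 higher and 3128 lower, of which 771 and 759 changed at least 1 on the log2 scale. Lower genes outnumbered higher ones with DESeq2 size factors (3376 against 3254), with the DESeq2 test (2641 against 2437) and with both genotypes fitted alone (4727 against 4672). The count rested on each library, being 4072 without Col replicate 1, 3843 without Col replicate 2, 3851 without ibm1 replicate 1 and 3709 without ibm1 replicate 2.

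The comparison of ibm1 jmj27 with Col asks the same of buds in which both demethylase transcripts are reduced. There 50.5% of all genes tested passed, the share to set beside the list counts. The 6 genes with the largest falls, among genes with a reference symbol and a mean log2 CPM of at least 1, had 0 or 1 counts in ibm1 jmj27. PGA4, a polygalacturonase gene, stood at 99.7 ± 5.87 CPM in Col and had 1 count in ibm1 jmj27, a ratio of 4725 (95% interval 848 to 1.87e+05). HA6, a proton pump gene, and VGDH2, a pectin methylesterase gene, also had 1 count there, ratios of 3346 (95% interval 600 to 1.32e+05) and 2322 (95% interval 416 to 9.17e+04). RALFL8, MSP2 and WRKY31 had 0 counts and were at least 250-fold, 157-fold and 111-fold lower. LHY had the largest rise by the same limits, at 7.39 ± 0.112, followed by the B-box genes BBX16 at 6.25 ± 0.400, BBX30 at a ratio of 70.3 (95% interval 23.8 to 343) and BBX31 at 5.55 ± 0.264, with FSD1 at 5.97 ± 0.262 and cPT4 at 5.58 ± 0.386 on the log2 scale.

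Of 27 measured pollen genes, 18 fell and 2 rose in ibm1 jmj27 (18 and 3 adjusted over the list alone), with a median of -1.80. VGD1 stood at -9.09 ± 0.217 and the calcium pump gene ACA9 at -5.65 ± 0.395 on the log2 scale. Each rests on 7 counts in ibm1 jmj27, so the SE understates counting error. ADF7 had 0 counts, at least 91.4-fold lower, and ADF10 had a ratio of 347 (95% interval 61.8 to 13749). Both encode actin-depolymerising factors of pollen. The list passed camera (adjusted p = 2.17e-06), with adjusted p = 0.240 with an estimated correlation. Of 28 tapetum and pollen wall genes, 15 fell and 1 rose by either adjustment, adjusted over the list alone or over all genes, with the pollen coat gene GRP17 falling by 3.90 ± 0.256, RPG1 by 2.18 ± 0.159 and QRT3 by 1.41 ± 0.0917 (camera adjusted p = 0.000104, and adjusted p = 0.606 with an estimated correlation). Against pds5 18 pollen genes fell and 3 rose with a median of -1.76 (camera adjusted p = 3.18e-06 over the 15 lists, and adjusted p = 0.0801 with an estimated correlation), while 10 tapetum genes rose and 4 fell. That comparison was chosen after seeing the data.

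Members of the meiotic recombination list fell in ibm1 jmj27 more often than they rose. Of 43 meiotic recombination genes, 20 fell and 2 rose (21 and 2 adjusted over the list alone). The crossover factor SHOC1 fell by 2.52 ± 0.250, MUS81, a crossover nuclease, by 0.71 ± 0.0943, and RAD50 by 0.63 ± 0.0797. ZYP1B of the synaptonemal complex, which has a near-identical copy, stood at -1.66 ± 0.224. The list passed camera (adjusted p = 0.00102), with adjusted p = 0.569 with an estimated correlation. Against pds5 it did not pass, with 4 higher and 9 lower members (camera adjusted p = 0.697). Of 22 cohesin genes, 12 fell and 1 rose by either adjustment, adjusted over the list alone included. PDS5B fell by 0.64, the loader gene SCC2 by 0.58 and PDS5E by 0.49, whereas PANS1 rose by 0.77 (camera adjusted p = 0.0286, and adjusted p = 0.600 with an estimated correlation). That list call ended without ibm1 jmj27 replicate 1 (adjusted p = 0.0960). Of 30 DNA and H3K9 methylation genes, 14 fell and 2 rose, the same as adjusted over the list alone. CLSY1 fell by 1.17, the DNA demethylase gene ROS1 by 1.01, the maintenance methyltransferase gene MET1 by 0.82 and NRPE1 by 0.67 (camera adjusted p = 0.00419, and adjusted p = 0.569 with an estimated correlation).

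Of the other groups in ibm1 jmj27, some moved 1 way and some both ways. Of 22 photosynthesis genes, 21 rose and 0 fell by either adjustment, adjusted over the list alone included, with LHCB1.1 at 2.95, LHCB3 at 1.88 and LHCB6 at 1.46 (camera adjusted p = 2.20e-09, and adjusted p = 0.569 with an estimated correlation). The demethylase list held 11 fallen and 0 risen genes of 17, the same as adjusted over the list alone, and JMJ30 fell by 4.64 and JMJ29 by 0.97 beside the targeted genes (camera adjusted p = 0.000193, and adjusted p = 0.593 with an estimated correlation). JMJ30 is itself known as a gene under clock control. The demethylase list holds the targeted IBM1 and JMJ27 and was not tested without them, so its call may partly restate the mutations. Of 13 defense genes 8 rose and 3 fell (8 and 4 adjusted over the list alone), with PR2 at 2.05 and PR5 at 2.30 (camera adjusted p = 0.0749). Of 17 DNA damage genes 8 rose and 4 fell by either adjustment, adjusted over the list alone included, with ANAC044 at 2.86 and SMR5 at 3.48, while BARD1 fell by 1.01 (camera adjusted p = 0.547). Floral organ identity held 5 risen and 8 fallen genes of 18 (6 and 8 adjusted over the list alone, adjusted p = 0.832), meiotic cell cycle 2 and 5 of 14 (2 and 6 adjusted over the list alone, adjusted p = 0.279), mitotic cell cycle 5 and 4 of 18 (5 and 5 adjusted over the list alone, adjusted p = 0.968), stomatal lineage 3 and 0 of 10 (adjusted p = 0.598) and heat stress 2 and 2 of 6 (adjusted p = 0.902), the last 2 counts unchanged when adjusted over the list alone. The mean of the floral list was -0.11 and its median 0.02 (test lower), and the mitotic list had a median of 0.06 and a mean of 0.03 with the test lower.

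In total 10881 genes passed in ibm1 jmj27, 5745 higher and 5136 lower, of which 1709 and 1776 changed at least 1 on the log2 scale. Lower genes outnumbered higher ones with DESeq2 size factors (5443 against 5356), with the DESeq2 test (4655 against 4349) and with both genotypes fitted alone (4709 against 4388). With each pair fitted alone, 9097 genes passed in ibm1 jmj27 and 9399 in ibm1, so the larger count in ibm1 jmj27 depended on the joint fit. With pds5 in place of Col, chosen after seeing the data, 8594 genes passed, 4126 higher and 4468 lower. There were 1930 genes higher and 2225 lower in ibm1 jmj27 against both Col and pds5. Both comparisons use the same ibm1 jmj27 libraries, so part of this agreement is built in, and no value for unchanged groups was simulated.

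The comparison of pds5 with Col asks which bud transcripts differ when PDS5 transcripts are reduced. There 49.0% of all genes tested passed, the share to set beside the list counts. Few pollen genes passed the test, whereas 19 of 28 tapetum and pollen wall genes fell and 10 of 13 defense genes rose, and neither of these lists passed with an estimated correlation (adjusted p = 0.594 and adjusted p = 0.569). The pathogenesis-related genes PR1, PR2 and PR5 rose by 6.26 ± 0.433, 2.84 ± 0.0881 and 2.33 ± 0.156 on the log2 scale. The genes with the largest rises, among genes with a reference symbol and a mean log2 CPM of at least 1, were bHLH38 and bHLH39, with ratios of 587 (95% interval 105 to 2.32e+04) and 306 (95% interval 54.6 to 1.21e+04) over a single Col count, BBX30 with a ratio of 228 (95% interval 77.9 to 1110), LHY at 7.68 ± 0.113, BBX31 at 7.50 ± 0.224 and BBX32 at 6.59 ± 0.201. By the same limits, which leave out PDS5A for want of a reference symbol, the largest falls were those of the clock-associated genes FKF1 (-6.42 ± 0.127), COR27 (-6.13 ± 0.172), ELF4 (-5.52 ± 0.193) and PRR5 (-4.37 ± 0.0891), of the auxin gene IAA32 (-4.61 ± 0.262) and of MEE14 (-4.39 ± 0.108).

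Of 28 tapetum and pollen wall genes, 19 fell and 2 rose in pds5 (22 and 2 adjusted over the list alone). MS1, a regulator of pollen wall formation, fell by 1.63 ± 0.142, QRT3 by 1.17 and the tapetal regulator BHLH89 by 0.96 (camera adjusted p = 1.90e-07, and adjusted p = 0.594 with an estimated correlation). Of 27 pollen genes 2 fell and 3 rose (2 and 1 adjusted over the list alone), AHA8 and MYB101 both falling by 1.21 (camera adjusted p = 0.733). Of 22 cohesin genes 10 fell and 0 rose (11 and 0 adjusted over the list alone), PDS5A, PDS5B, PDS5C and PDS5E among them (camera adjusted p = 0.000937, and adjusted p = 0.569 with an estimated correlation). The cohesin list had a mean of -0.79 and a median of -0.24. It was not tested without the PDS5 genes, so its call may partly restate the mutation. Of 43 meiotic recombination genes 17 fell and 1 rose (17 and 0 adjusted over the list alone), with RAD50 falling by 0.73, RECQ4A by 0.65 and PTD by 0.83 (camera adjusted p = 0.00567, and adjusted p = 0.569 with an estimated correlation). Of 30 DNA and H3K9 methylation genes 16 fell and 4 rose (19 and 4 adjusted over the list alone), with NRPE1 falling by 1.26, CLSY1 by 1.18 and VIM1 by 0.58 (camera adjusted p = 0.00292, and adjusted p = 0.569 with an estimated correlation). LHY was higher by 7.68 on the log2 scale in these pds5 libraries. Whether a different mix of bud stages moved these lists in pds5 was not tested.

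Of 13 defense genes 10 rose and 1 fell in pds5 by either adjustment, adjusted over the list alone included (camera adjusted p = 0.000180, and adjusted p = 0.569 with an estimated correlation). Of 22 photosynthesis genes 15 rose and 3 fell (16 and 3 adjusted over the list alone), with LHCB2.1 at 2.35 and RCA, the rubisco activase gene, at 1.21 (camera adjusted p = 0.00115, and adjusted p = 0.606 with an estimated correlation). Of 17 DNA damage genes 4 rose and 2 fell (3 and 2 adjusted over the list alone). SMR5 rose by 4.02, ANAC044 by 2.77, and ANAC085 was at least 16.8-fold higher than in Col, where it had 0 counts, while the list's median was -0.06 and its mean 0.82 (camera adjusted p = 0.764). Floral organ identity held 6 risen and 5 fallen genes of 18, PI rising by 0.87 and AG and FLC falling by 0.72 and 1.55 (adjusted p = 0.864). Stomatal lineage held 5 and 2 of 10 (adjusted p = 0.405), the demethylase list 0 and 5 of 17 (adjusted p = 0.111), meiotic cell cycle 1 and 4 of 14 (adjusted p = 0.146), mitotic cell cycle 4 and 3 of 18 (adjusted p = 0.968) and heat stress 0 and 0 of 6 (adjusted p = 0.832), all of these counts unchanged when adjusted over the list alone. The median, mean and test differed in sign for the floral list (0.02, -0.04 and higher), the mitotic list (-0.04, 0.03 and lower) and the heat list (0.01, 0.03 and lower). In total 10566 genes passed in pds5, 5564 higher and 5002 lower, of which 1732 and 993 changed at least 1 on the log2 scale.

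The comparison of ibm1 jmj27 with ibm1 asks what differs beside the jmj27 mutation, with LHY higher by 4.66 in ibm1 jmj27. Here 45.5% of all genes tested passed, the share to set beside the list counts. JMJ27 fell by 3.13 ± 0.0865, PDS5A rose by 1.09 ± 0.0826 and PDS5B fell by 0.69 ± 0.0900, while IBM1 was at -0.04 (adjusted p = 0.757). Among the largest falls by the limits used for the other comparisons, PGA4 had 1 count against 32.2 ± 0.987 CPM in ibm1, a ratio of 1530 (95% interval 274 to 6.05e+04), and ADF7 had 0 counts, at least 40.5-fold lower. Besides LHY at 4.66 ± 0.0913, the largest rises by those limits were those of MSRB9 (4.09 ± 0.350), BSMT1 (3.74 ± 0.470), the tapetal protease gene CEP1 (3.46 ± 0.420), CML41 (3.28 ± 0.186) and QQS (3.19 ± 0.193). TDM1, which was lower in ibm1 than in Col, rose by 1.93 ± 0.286.

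Of 27 pollen genes, 13 fell and 2 rose in ibm1 jmj27 against ibm1 (14 and 2 adjusted over the list alone), VGD1 at -7.48 ± 0.249 and AHA8 rising by 1.06 ± 0.110 (camera adjusted p = 0.000286, and adjusted p = 0.240 with an estimated correlation). Of 43 meiotic recombination genes 20 fell and 0 rose by either adjustment, adjusted over the list alone included, with SHOC1 falling by 2.27, PTD by 1.09 and the axis gene ASY3 by 0.53 (camera adjusted p = 0.00155, and adjusted p = 0.569 with an estimated correlation). Of 30 DNA and H3K9 methylation genes 13 fell and 4 rose, the same as adjusted over the list alone, with ROS1 falling by 0.81 and MET1 by 0.74 (camera adjusted p = 0.0286, and adjusted p = 0.594 with an estimated correlation). That call ended without ibm1 jmj27 replicate 1 (adjusted p = 0.0668). Of 28 tapetum and pollen wall genes 8 rose and 4 fell by either adjustment, adjusted over the list alone included, with GRP17 at -2.94 and RPG1 at -1.63 (camera adjusted p = 0.832). Photosynthesis genes rose in 14 of 22 cases and fell in 0 (15 and 0 adjusted over the list alone, camera adjusted p = 0.00155, and adjusted p = 0.606 with an estimated correlation), and defense genes rose in 6 of 13 and fell in 1 by either adjustment, adjusted over the list alone included (camera adjusted p = 0.0221, and adjusted p = 0.586 with an estimated correlation). By either adjustment, adjusted over the list alone included, the demethylase list held 10 fallen and 0 risen genes of 17 (camera adjusted p = 0.00124, and adjusted p = 0.594 with an estimated correlation), and the clock list 8 fallen and 4 risen genes of 12 (camera adjusted p = 0.0268, and adjusted p = 0.600 with an estimated correlation). The demethylase list holds the targeted JMJ27 and was not tested without it.

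Of the other lists in this comparison, mitotic cell cycle genes rose in 9 of 18 cases and fell in 0 (camera adjusted p = 0.0574), with MAD2 of the spindle checkpoint at 0.74 and CYCD3;1 at 0.50. Cohesin genes rose in 4 and fell in 10 of 22 cases (5 and 12 adjusted over the list alone, adjusted p = 0.302), DNA damage genes in 7 and 4 of 17 (8 and 4 adjusted over the list alone, adjusted p = 0.764), floral organ identity genes in 7 and 3 of 18 (adjusted p = 0.513), meiotic cell cycle genes in 3 and 2 of 14 (adjusted p = 0.850), heat stress genes in 4 and 1 of 6 (adjusted p = 0.400) and stomatal lineage genes in 1 and 0 of 10 (adjusted p = 0.832), the last 4 counts and the mitotic counts unchanged when adjusted over the list alone. The meiotic cell cycle list had a median of -0.03 and a mean of 0.23 (test higher), and the stomatal list 0.02 and -0.01 (test higher). In total 9798 genes passed, 4894 higher and 4904 lower, of which 1164 and 1437 changed at least 1 on the log2 scale. Without ibm1 replicate 2 the count was 6451. Across all 4 comparisons 25 of the 60 list tests passed with the preset correlation and 0 with an estimated one, of which 4 had an unadjusted p under 0.05.

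**Figure D3:**
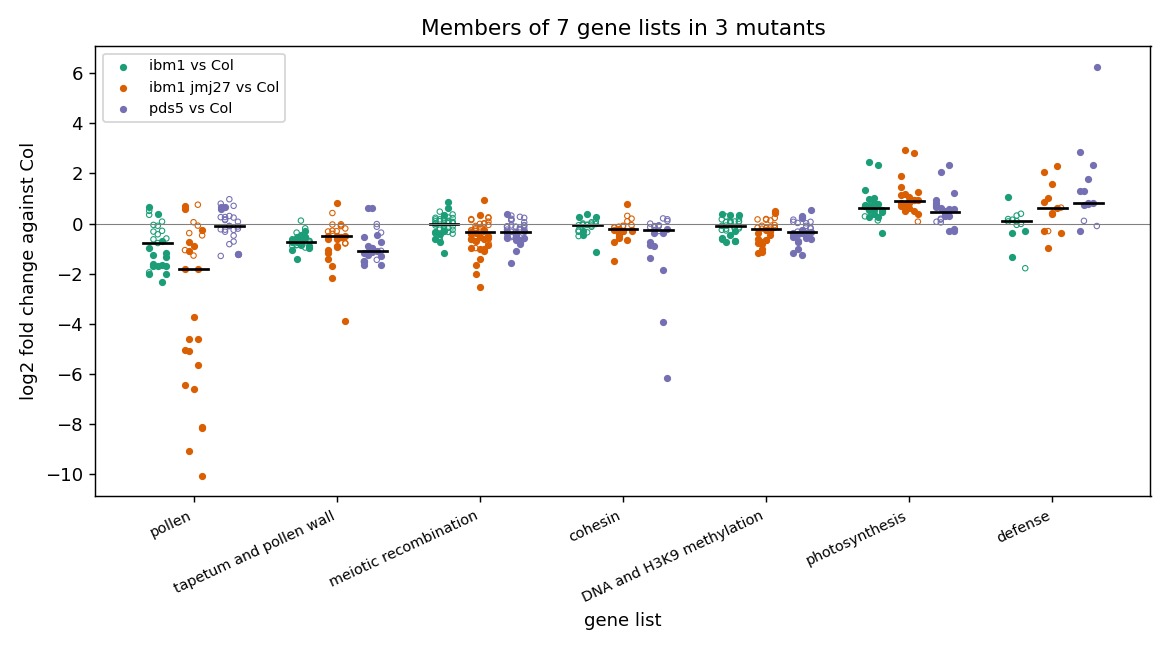
Log2 fold changes against Col (vertical axis) of the members of 7 gene lists in 3 mutants, with filled points for genes past the test, open points for the rest and a black line at the median, fitted values being shown for genes at 0 counts. The pollen list has a median of -1.80 in ibm1 jmj27 and -0.09 in pds5.

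The mutants were also compared through the genes they shared. Genes that changed the same way in ibm1 and ibm1 jmj27 numbered 4066, against 1693 for independent lists, while 525 changed in opposite directions. For ibm1 and pds5 they numbered 3895 against 1643, with 517 opposite, and for ibm1 jmj27 and pds5 6480 against 2676, with 448 opposite. Unchanged groups simulated against the Col libraries shared at most 2 genes in either direction. Those groups held no changed genes, so little could pass the test in them. They cannot show how many shared calls the Col libraries add where many genes change. The covariance of log2 fold changes was 0.511, 0.391 and 0.556 for the 3 pairs, against 0.0419, 0.0420 and 0.0425 in simulated unchanged groups. The correlations across genes were 0.555, 0.606 and 0.480, against 0.502, 0.510 and 0.524 in the simulated groups. A split of the 2 Col libraries would leave each mutant 1 control library and was not made, so part of the excess overlap may come from these shared controls. LHY and CCA1 rose and TOC1, GI, ELF4 and LUX fell in all 3 mutants. Without Col replicate 1 and without Col replicate 2 the shared genes numbered 2626 and 2411 for ibm1 and ibm1 jmj27, and 2507 and 2280 for ibm1 and pds5.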

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

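The use of pds5 in place of Col for ibm1 jmj27, for the count of genes and for the gene lists, was chosen only after the result was seen, and it gave 8594 genes. With an absolute log2 fold change of at least 1, the counts were 1530 (ibm1 against Col), 3485 (ibm1 jmj27 against Col), 2725 (pds5 against Col) and 2601 (ibm1 jmj27 against ibm1), and the shared genes numbered 981 for ibm1 and ibm1 jmj27, 793 for ibm1 and pds5 and 1435 for ibm1 jmj27 and pds5, since the criterion is stricter. An adjusted p under 0.01 gave 4017 genes in ibm1. Leaving out 1 library gave 3709 to 4072 genes in ibm1, 7954 to 12026 in ibm1 jmj27, 7575 to 8197 in pds5 and 6451 to 10955 for ibm1 jmj27 against ibm1, with the lone library of a genotype assumed to vary like the others. Without a Col library the shared genes numbered 2411 to 2626, 2280 to 2507 and 4414 to 4792 for the 3 pairs in that order. Without ibm1 jmj27 replicate 2 the counts of its comparisons rose, and the cause of these shifts was not tested. With an estimated correlation 0 of the 60 list tests passed camera, 4 having an unadjusted p under 0.05, whereas fry passed 33, and the cause was not tested. Leaving out 1 library left 22 to 27 list calls. The DESeq2 size factors, the missing filter, the DESeq2 test, the genotypes fitted alone and the fit without robust estimation kept each count within 1.5 times, and no call reversed under any of these or without a library. DESeq2 gave 5078, 9004, 8690 and 7775 genes in the order used for the counts. The genotypes fitted alone gave 9399, 9097, 12000 and 8011 in the same order. Fitted so, ibm1 no longer had fewer genes than ibm1 jmj27, and the order of these counts depended on the joint fit. These settings moved the share of higher calls by at most 5.18 percentage points, though the direction with more calls turned in places. In ibm1 3552 higher and 3128 lower became 3254 and 3376 with DESeq2 size factors and 2437 and 2641 with the DESeq2 test and 4672 and 4727 with the genotypes fitted alone, and in ibm1 jmj27 5745 and 5136 became 5356 and 5443, 4349 and 4655, and 4388 and 4709. Among 2520 values of named genes under other settings 69 lost their call in ibm1, 17 in ibm1 jmj27, 13 in pds5 and 18 for ibm1 jmj27 against ibm1, and 4 in ibm1 and 1 in ibm1 jmj27 gained one. The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.00671 to 0.101, with only 2 pairs. A replicate block gave 7027, 11137, 10846 and 10120 genes in the same order and ended 1 list call, meiotic cell cycle in ibm1 (adjusted p = 0.0515). Depth limits low genes: 3 counts equal 0.115 to 0.154 CPM in these libraries.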

Other observations

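The tests on clock phase in harvested buds and on late flower genes used lists written after the data were seen but before those genes were looked at, and the tests on LHY in pds5, on pollen genes in pds5 and on PDS5A were chosen only after the result was seen. Bootstrap intervals below resample the genes of a list, not libraries, so they do not measure the spread between samples or plants.

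Genes of the iron deficiency response, a list written after the data were seen but before these genes were looked at, were higher in ibm1 and pds5. All 9 rose in ibm1, with a median of 2.08 on the log2 scale, and all 9 rose in pds5, with a median of 2.33. BHLH100 rose by 3.49 and 2.33, the iron reductase gene FRO3 by 1.85 and 1.49, and the iron sensor gene BTS by 0.96 and 0.95. In ibm1 jmj27 3 of the 9 rose, PYE by 0.95, OPT3 by 0.36 and NAS4 from 3 to 19 counts (ratio 5.73, 95% interval 1.69 to 30.2), and BTS fell, and against pds5 all 9 were lower there, with a median of -1.95. The ferritin genes FER1, FER3 and FER4, which encode iron stores, fell in ibm1 and pds5, with FER4 at -0.71 and -1.64, and in ibm1 jmj27 FER3 stood at -0.74 and FER4 at -0.34 while FER1 did not pass. AT1G13609, also picked after its values were seen, had 597 counts in ibm1 and 1416 in pds5 against 0 in Col, at least 199-fold and 402-fold higher. It passed in ibm1 jmj27 as well, with 9 counts, at least 2.71-fold higher (adjusted p = 0.00675). In ibm1 jmj27 BTS was at -0.25 (adjusted p = 0.0334) and FRO3 at -0.11 (adjusted p = 0.406).

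AT1G36240, picked after its values were seen, had 3155 counts in Col, 0 in ibm1, 3 in ibm1 jmj27 and 2 in pds5. The labels do not say whether the mutants and the Col plants share a background, and this was not tested. A difference in background stays open for every comparison with Col and for the overlaps between mutants.

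Clock genes moved in all 3 mutants. Buds collected at different times of day may account for this. Further morning genes such as LNK2 and COL1 and further evening genes such as PRR3 and GRP7 parted in each mutant. They did so by 3.37 on the log2 scale in ibm1 (95% bootstrap interval 2.44 to 4.01), 6.84 in ibm1 jmj27 and 5.97 in pds5. An effect of a genotype on the clock would part them as well, so this test cannot separate it from harvest time. A loss of the IBM1 or JMJ27 transcripts does not account for the pattern in pds5, where neither passed the test and LHY rose by 4.95 more than in ibm1, beyond 3 standard errors (0.488). Harvest time, day length and an effect of each genotype on the clock all stay open, since the labels give neither times nor day lengths per library.

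Most pollen genes of the list were lower in ibm1 jmj27, with a median of -1.80. A difference in clock phase between Col and ibm1 jmj27 could lower them. In pds5 LHY lay near its ibm1 jmj27 level, and the further morning and evening genes parted by 5.97 against 6.84 in ibm1 jmj27. The pollen median in pds5 was -0.0915 (95% bootstrap interval -0.24 to 0.26). A clock shift like that of pds5 thus did not go with lower pollen genes. Yet 10 of the 12 clock genes passed the test between these mutants (median -0.55, camera adjusted p = 0.00185, and adjusted p = 0.502 with an estimated correlation). Any clock difference of ibm1 jmj27 beyond that of pds5 therefore cannot be told apart from the genotype. The condition that the clock lists be alike was added after its value was seen, and the test itself was chosen after a first one left the question open, in which the pollen median against pds5 was -1.76 and its interval of -5.30 to -0.32 held the bound of -1. An effect of the genotype on pollen stays open, as do fewer late-stage buds, since the 8 measured late flower genes had a median of -0.89 against Col with an interval of -2.25 to 2.30 that holds the bound of -1, and of -1.77 against pds5, where 6 fell and 1 rose.

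PDS5A was lower in ibm1 but not in ibm1 jmj27, where it passed at -0.17 without replicate 2. Admixed pds5 RNA would need a share of 55.7% and would have put PDS5B at -1.06, but PDS5B was at 0.0523 in ibm1. PDS5E, lower by 0.88 in pds5, did fall in ibm1, by 0.46 (adjusted p = 0.000185). PDS5C, lower by 1.84 in pds5, stood at -0.13 in ibm1 (adjusted p = 0.243). A change over the neighbouring genes is argued against by their median of 0.16 over 20 genes (95% bootstrap interval -0.18 to 0.29), though 9 of them passed the test and 3 of these were lower, AT5G47740 by as much as PDS5A (-1.18). An effect of JMJ27 loss on PDS5A in the ibm1 background and a difference between plant lineages may each account for the pattern, and neither was tested.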
